A study of Mus musculus with 11 samples.

How the data were processed

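Gene expression was measured by RNA sequencing in ILC2 and Th2 cells sorted from mouse lung, in 6 and 5 libraries. RNA was prepared with the RNeasy Micro Plus kit, amplified and made into libraries with the Ovation V2 and Ultralow V2 kits, and sequenced as single reads of 50 bp. The deposited values are raw counts per Ensembl gene, made by the authors from reads aligned to mm10; per the submitters' processing notes TopHat2 2.0.11, HTSeq and DESeq were used, without a statement of which step each served. The annotation release, the strand setting and any filters are not given in the sources used here, so counts of antisense and overlapping genes are uncertain. Every file held the same 37991 gene IDs with whole-number counts, of which 32919 were given a name and 32938 a position from GENCODE M21 on GRCm38, the assembly of mm10. IDs without a name held 0.990% to 3.77% of the counts of a library.

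Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, whose factors ran from 0.813 to 1.33, and a quasi-likelihood model with robust dispersion was fitted with cell type and sort date as terms. The date term takes up the difference between the 2 infections, since both cell types were sorted on each date. A positive log2 fold change is higher in ILC2, or higher in August for the date term. The interaction of cell type and date was fitted in a model of its own. P-values were adjusted by Benjamini-Hochberg, and a gene with an adjusted p under 0.05 is said to be called, or to have passed the test. Levels are CPM on the TMM-scaled totals, given as mean and SD over libraries. Principal components were taken from log2 CPM with a prior count of 2.

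Gene lists were 16 lists of functions and 7 of other cell types, with 455 members, of which 6 did not match a gene name. Each list was summarised by its members past the threshold, with the adjustment over all genes and over the list alone. Lists with at least 3 tested members were also tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists. Changes of lists between the dates were tested with fry within each cell type, and the difference between the cell types likewise; these tests were chosen after seeing the data. The lists, the comparisons with their tests of genes and the rule for naming genes were set before the data were examined.

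The rule named the 12 genes with the largest log2 fold change in each direction among those past the threshold with a mean log2 CPM of at least 4 and no overlap between the libraries of the cell types, leaving out gene models, antigen receptor segments, and mitochondrial, ribosomal RNA, small nucleolar and microRNA genes. It also named any tested member of a list, with preference for the 2 largest changes in each direction, Xist and Y-linked genes as a check of the replicate numbers, and the 4 genes with the smallest p for the date and for the interaction. Trac, Trbc1 and Trbc2, along with the genes counted by DESeq2 for the date, were named after their values were seen.

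Depth ran from 8348899 to 44221947 counts per library, with 17039 to 21102 genes detected. The 10 highest genes took 31.2% to 55.7% of the counts. The common biological coefficient of variation was 0.395. The procedure was tested on simulated data of the same size with 200 changed genes: for the cell types 29.8% of 2-fold and 84.2% of 4-fold changes were recovered, and 4.4% of calls were false.

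Alternatives tried were RLE and upper quartile scaling, no filter on low counts, DESeq2 1.42.0, limma 3.58.1 with voom, a test against a fold of 1.5, counts thinned to the smallest library, each library left out in turn, no date term, each sort date alone, and the replicate number as a block. After the data were seen, mitochondrial genes left out, a term for sex and the omission of ILC2 replicates 2 and 7 and Th2 replicate 1 were added. For other splits of the samples, 100 of the 462 splits into 6 and 5 and 100 of the 330 splits into 7 and 4 were drawn with a fixed seed. Tables and figures were made with pandas 2.3.3, numpy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9. No library was left out of the main comparisons.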

Results

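Messenger RNA was profiled in 2 populations of type 2 lymphocytes from the lungs of C57BL/6 mice, 14 days after subcutaneous infection with 500 larvae of Nippostrongylus brasiliensis, a nematode whose larvae pass through the lung. The mice were homozygous for Red5, a fluorescent reporter inserted at the interleukin-5 locus, so that reporter-positive cells are cells with an active Il5 locus. Group 2 innate lymphoid cells (ILC2) were sorted as lineage-negative, CD4/CD5-negative, Thy1-positive, Red5-positive cells, and T helper 2 (Th2) cells as CD4/CD5-positive, Thy1-positive, Red5-positive cells. The series text speaks of 7 mice and 2 independent infections, and the labels give 2 sort dates, in June and in August of the same year. There were 6 ILC2 libraries, 4 sorted in June and 2 in August, and 5 Th2 libraries, 3 sorted in June and 2 in August. The labels number the replicates but do not say which mouse a library came from, so p-values measure the spread between libraries as labelled.

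Library totals ran from 8348899 counts in Th2 replicate 1 to 44221947 in ILC2 replicate 2. Mitochondrial genes took 28.4% to 52.0% of the counts. ILC2 replicate 2 had the lowest share, while the other ILC2 libraries held 42.0% to 49.3%. The first principal component of the log2 CPM (counts scaled to the library total) took 36.6% of the variance and placed every ILC2 library, from -86.4 to -24.9, apart from every Th2 library, from 39.2 to 79.4. On the next component, with 21.1%, ILC2 replicate 2 at 79.5 and ILC2 replicate 7 at -90.5 lay far from the other ILC2 libraries, which spanned 5.27 to 26.2.

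**Figure D1:**
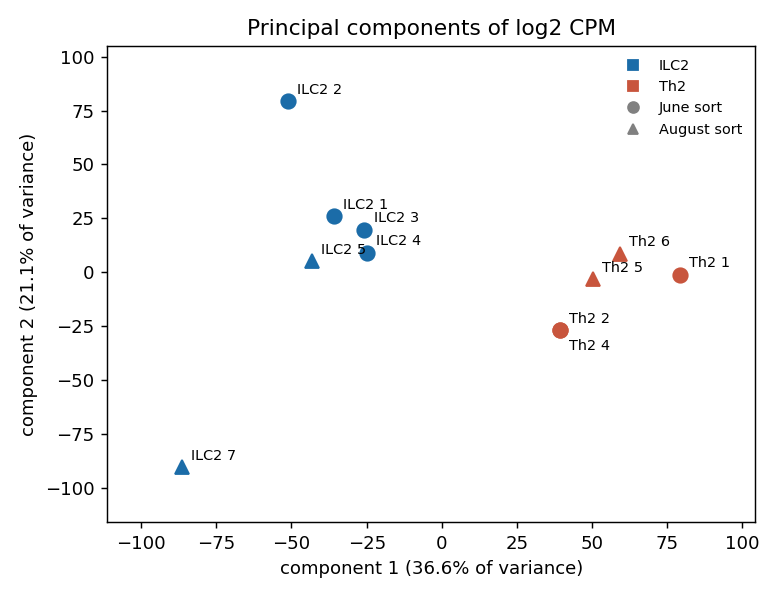
Scores of the 11 libraries on the first 2 principal components of log2 CPM (axes in score units, with the percent of variance); colour gives the cell type and shape the sort date. The cell types separate on component 1, and ILC2 replicates 2 and 7 mark the ends of component 2.

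The main comparison asked how innate and adaptive cells that share an active type 2 cytokine locus differ in the same infected tissue. ILC2 carried far more transcript of the stem cell factor receptor Kit, of Alox5, the 5-lipoxygenase of leukotriene synthesis, and of the scavenger receptor Stab2. Th2 cells carried the T cell surface proteins Cd6, Cd5, Cd4 and Cd2, the costimulatory ligand Cd40lg and the CD3 subunits of the T cell receptor complex, Cd3e and Cd3d. Kit stood at 235 ± 118 CPM (mean ± SD, n = 6) in ILC2 and 8.96 ± 3.72 (n = 5) in Th2, a 26.3-fold difference, and Alox5 at 81.4 ± 12.8 against 3.21 ± 1.69 CPM, a 25.6-fold difference. Cd6 stood at 0.741 ± 0.629 CPM in ILC2 and 129 ± 16.3 in Th2, 191-fold apart. Of 13560 genes tested with edgeR, 530 were higher in ILC2 and 453 higher in Th2, 7.25% of the genes, and 446 and 363 of them differed more than 2-fold. For 998 genes, or 7.36%, the libraries of the 2 cell types did not overlap at all, against 0.433% by chance. With the libraries of 1 sort date only, 310 and 272 genes were called in June and 126 and 113 in August. ILC2 replicates 2 and 7 and Th2 replicate 1 stand apart from their groups. Without them, a choice made after seeing the data, 1067 genes were called, 799 of them among the 983.

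By the rule fixed for naming genes, the 12 largest changes higher in ILC2 were Stab2, Adam12, Pde7b, Ccdc184, Kit, Alox5, Slc27a6, Lpcat2, Cntn1, Zcchc14, Plekhg1 and Spry2, with log2 fold changes from 3.76 to 6.07. Stab2 led them with 6.07 ± 0.58 (± SE, edgeR adjusted p = 2.37e-05), at 102 ± 72.9 CPM in ILC2 and 1.39 ± 1.03 in Th2. Adam12, a membrane metalloprotease, was higher by 4.90 ± 0.34 (adjusted p = 2.54e-06). Pde7b, a cyclic AMP phosphodiesterase, differed by 4.90 ± 0.44, and Lpcat2, an acyltransferase that forms platelet-activating factor, by 4.18 ± 0.53. Spry2, an inhibitor of receptor tyrosine kinase signalling, was higher by 3.76 ± 0.24 (adjusted p = 1.15e-06). The 12 largest changes in the other direction were Cd6, Cd4, Cd5, Cd40lg, Slfn1, Cd3e, Slamf1, Cd3d, St8sia1, Cd2, Themis and Angptl2, from -4.77 to -7.58. Slfn1, a Schlafen family gene, differed by -6.45 ± 0.56, and Slamf1, a lymphocyte activation receptor, by -5.33 ± 0.39 (adjusted p = 3.59e-06). Cd4 and Cd5 belong to the sorting gate, and their values of -7.37 ± 0.50 and -7.35 ± 0.73 check the sort. Stab2 gave 6.94 without Th2 replicate 2, Cd5 -8.47 without ILC2 replicate 7 and Angptl2 -4.07 without Th2 replicate 1. In mm10 coordinates Kit (ENSMUSG00000005672) lies on chromosome 5 at 75574916 to 75656722, Alox5 (ENSMUSG00000025701) on chromosome 6 at 116410077 to 116461178, and Cd6 (ENSMUSG00000024670) near Cd5 on chromosome 19 at 10789341 to 10830058.

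**Figure D2:**
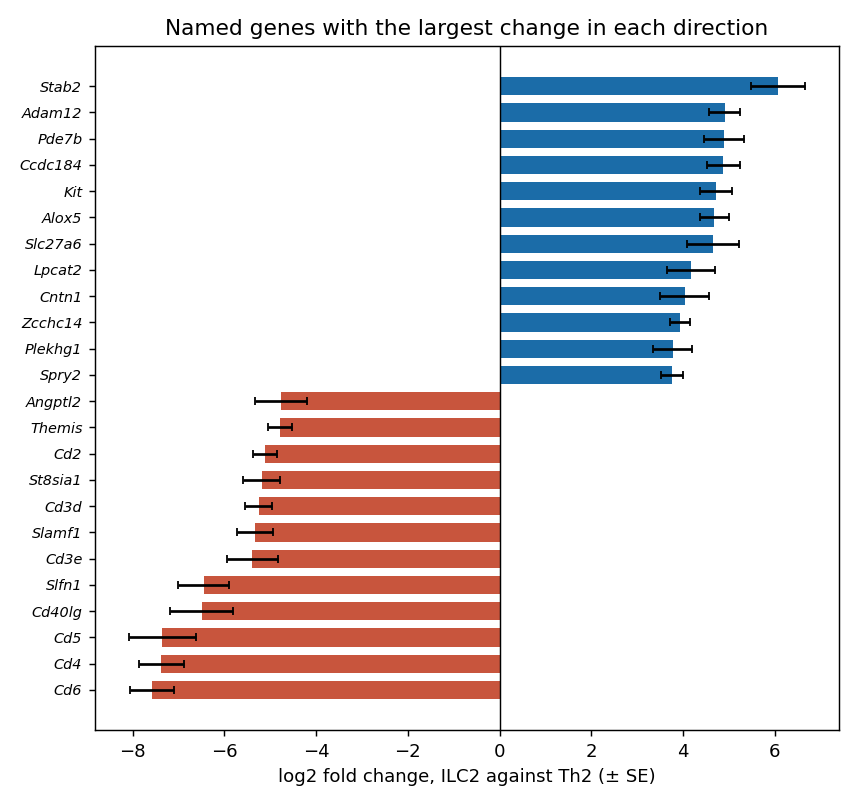
Log2 fold change of ILC2 against Th2 for the 24 named genes (bars, ± SE from the edgeR model; 6 ILC2 and 5 Th2 libraries). Bars to the right, up to 6.07 for Stab2, are higher in ILC2 and bars to the left, down to -7.58 for Cd6, higher in Th2.

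Genes of the T cell receptor complex and its signalling divided into those that ILC2 nearly lacked and those that both cell types carried. Of 22 members tested, 10 were higher in Th2 and 0 in ILC2 (1 higher in ILC2 and 13 in Th2 adjusted over the list alone; camera adjusted p = 8.55e-23, adjusted p = 0.00168 with an estimated correlation). Besides Cd3e at -5.39 ± 0.56 and Cd3d at -5.25 ± 0.29, the thymocyte selection gene Themis differed by -4.79 ± 0.26 and the zeta chain Cd247 by -4.38 ± 0.23. Cd3g differed less, -2.06 ± 0.17, and kept 63.6 ± 12.8 CPM in ILC2. The kinase Lck (-1.63 ± 0.18) and the adaptor Lat (-1.26 ± 0.18) were also higher in Th2. The kinase Zap70 (-0.08 ± 0.23, adjusted p = 0.906) did not pass the test, at 51.5 ± 19.3 CPM in ILC2 and 54.4 ± 8.96 in Th2.

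Coreceptors and costimulatory genes were higher in Th2 for 13 of 20 members and in ILC2 for 0 (0 higher in ILC2 and 15 in Th2 adjusted over the list alone; camera adjusted p = 1.18e-31, adjusted p = 0.00168 with an estimated correlation). Cd28, the main costimulatory receptor, stood at 40.3 ± 20.3 CPM in ILC2 and 977 ± 199 in Th2 (-4.60 ± 0.35, adjusted p = 4.41e-06). Cd40lg, by which T cells help B cells, differed by -6.49 ± 0.68, and the inhibitory receptor Lag3 by -3.65 ± 0.64. Th2 replicate 1 held 134 CPM of Lag3 against 11.1 to 36.1 in the other Th2 libraries, and without it the value was -2.60. Icos was 2.48-fold higher in Th2 yet abundant in both, at 423 ± 69.3 CPM in ILC2 and 1056 ± 203 in Th2. The checkpoint genes Ctla4 (-0.48 ± 0.55, adjusted p = 0.715) and Pdcd1 (0.42 ± 0.18, adjusted p = 0.251) did not pass the test.

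The canonical type 2 cytokines Il13, Il4 and Il5 did not pass the test with all libraries, which does not show equal levels. A set of other cytokine genes was higher in ILC2. Il13 reached 1039 ± 1084 CPM in ILC2 and 486 ± 258 in Th2 (0.97 ± 0.53, adjusted p = 0.364), and Il4 19.6 ± 20.8 against 35.7 ± 27.1 CPM (-0.95 ± 0.56, adjusted p = 0.409). Il5, whose locus carries the reporter and was the sorting criterion, stood at 134 ± 154 against 41.9 ± 17.3 CPM (1.46 ± 0.59, adjusted p = 0.202). ILC2 replicate 2 lay apart in these genes, with Il13 at 3243 CPM against 519.9 to 769.7 in the other ILC2 libraries; without it Il13 gave 0.31 and Il5 0.75, neither past the threshold, and Il4 was higher in Th2 with adjusted p = 0.0460. Bmp2, a bone morphogenetic protein, was higher in ILC2 by 5.99 ± 0.76, Csf2, which encodes GM-CSF, by 3.47 ± 0.41 (101 ± 65.7 against 9.08 ± 5.55 CPM, adjusted p = 0.000112), Tnf by 2.69 ± 0.47 and Il2, the T cell growth factor, by 1.84 ± 0.36. Lta, Lif, Ltb and the epithelial growth factor Areg (1.59 ± 0.43, adjusted p = 0.0412) made up the 8 of 20 members higher in ILC2. Il3 (-4.10 ± 1.03), the anti-inflammatory Il10 (-3.95 ± 0.92) and the macrophage growth factor Csf1 (-1.98 ± 0.30, adjusted p = 0.000757) were higher in Th2. The cytokine list held 10 higher in ILC2 and 3 in Th2 adjusted over the list alone; camera adjusted p = 0.00241, adjusted p = 0.0969 with an estimated correlation. Within sort dates 3 members were higher in ILC2 in June and 4 in August. With single libraries left out, the calls of Areg and Ltb were lost in 7 and 5 of 11 fits (adjusted p up to 0.116 and 0.0749). That of Il3 was lost without ILC2 replicate 1, 3 or 4 (up to 0.0686) and that of Il10 without ILC2 replicate 5 or Th2 replicate 1 (up to 0.151). The value of Il3 was -3.45 without ILC2 replicate 2 and -3.41, -4.92 and -5.01 without Th2 replicates 1, 5 and 6, and that of Il10 was -4.63 without ILC2 replicate 2 and -3.21 without Th2 replicate 1.

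**Figure D3:**
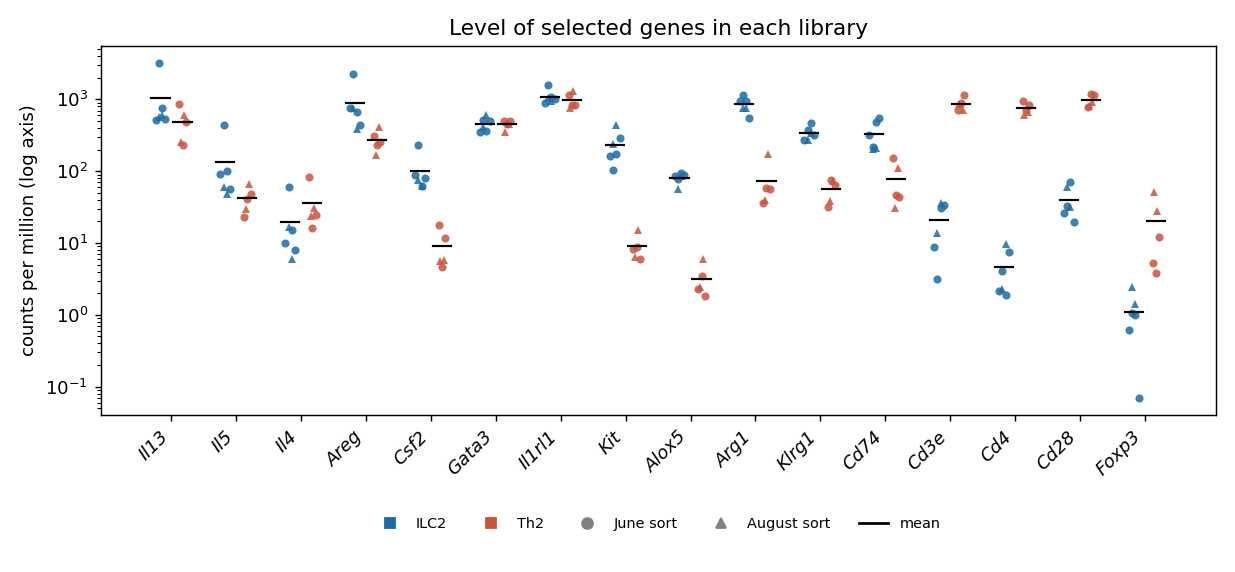
CPM of selected genes in each library on a log axis; colour gives the cell type, circles the June sort, triangles the August sort and black lines the group means (6 ILC2 and 5 Th2 libraries). Il13, Gata3 and Il1rl1 overlap between the cell types, whereas Kit, Alox5, Arg1, Cd3e and Cd4 do not.

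The type 2 cytokine genes lie together on chromosome 11 of mm10, Il4 at 53602982 to 53618669, Il13 at 53631324 to 53634702 and Il5 at 53720794 to 53725106, with Rad50 between Il13 and Il5. Gata3, the transcription factor that directs type 2 cytokine genes, stood at 455 ± 98.3 CPM in ILC2 and 454 ± 62.7 in Th2 (0.01 ± 0.18, adjusted p = 0.994), with -0.18 in June and 0.34 in August. Il1rl1, the receptor for the alarmin IL-33, stood at 1088 ± 245 against 977 ± 239 CPM (0.15 ± 0.21, adjusted p = 0.780). Crlf2 (-0.37 ± 0.24), Il2ra (0.09 ± 0.47) and Il7r (0.67 ± 0.20, adjusted p = 0.0691, and 0.0320 without Th2 replicate 4) did not pass the test either. Among the 24 cytokine receptors, 5 were higher in ILC2. They were Kit, the IL-25 receptor Il17rb (2.25 ± 0.38, adjusted p = 0.00215), the death receptor family member Tnfrsf25 (1.80 ± 0.29), Il18rap (1.16 ± 0.25) and Il9r (1.09 ± 0.31). Il6ra (-4.25 ± 0.39, adjusted p = 1.81e-05) and Il21r (-1.43 ± 0.16) were higher in Th2. The receptor list held 6 higher in ILC2 and 2 in Th2 adjusted over the list alone; camera adjusted p = 0.0730, adjusted p = 0.173 with an estimated correlation. The call of Il9r was lost in 8 of 11 fits with a library left out (adjusted p up to 0.155).

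Most lineage transcription factors did not pass the test, with 3 of 30 higher in ILC2 and 4 in Th2 (5 higher in ILC2 and 8 in Th2 adjusted over the list alone; camera adjusted p = 0.318, adjusted p = 0.434 with an estimated correlation). Lmo4, a LIM domain cofactor, was higher in ILC2 at 143 ± 79.1 against 19.9 ± 7.73 CPM (2.84 ± 0.39, adjusted p = 0.000418), with Id2, the inhibitor of E proteins needed for innate lymphoid development (0.83 ± 0.21), and Bhlhe40 (0.69 ± 0.19). The chromatin organiser Satb1 (-2.19 ± 0.36, adjusted p = 0.00151), the CD4 lineage factor Zbtb7b (-1.19 ± 0.19), Runx1 (-0.78 ± 0.19) and the aryl hydrocarbon receptor Ahr (-0.80 ± 0.20) were higher in Th2. Rora, required for ILC2 development, gave 0.91 ± 0.34, adjusted p = 0.158 (0.0395 without Th2 replicate 2), Bcl11b -0.52 ± 0.20, adjusted p = 0.163, and Tcf7 -1.04 ± 0.32, adjusted p = 0.0801 (0.00187 without Th2 replicate 1). Calls of Id2, Bhlhe40, Runx1 and Ahr were lost in 7, 9, 4 and 8 of 11 fits with a library left out, with adjusted p up to 0.0937, 0.141, 0.0764 and 0.115.

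Of 12 members of the list for other helper lineages, 6 were higher in Th2 and 1 in ILC2 (2 higher in ILC2 and 6 in Th2 adjusted over the list alone; camera adjusted p = 0.00176, adjusted p = 0.230 with an estimated correlation). The Th1-associated chemokine receptor Cxcr3 stood at 0.437 ± 0.449 against 12.8 ± 10.3 CPM (-4.48 ± 0.69), the regulatory T cell factor Foxp3 at 1.09 ± 0.799 against 20.3 ± 20.1 CPM (-3.71 ± 0.49, adjusted p = 0.000295), Ifng at 0.668 ± 0.295 against 7.29 ± 4.92 CPM and the Th1 factor Tbx21 at 0.801 ± 0.297 against 3.57 ± 1.22 CPM. Ikzf4 (-1.07 ± 0.23) and the follicular helper receptor Cxcr5 (-1.73 ± 0.42, lost without Th2 replicate 1 or 5, adjusted p up to 0.0714) were also higher in Th2. Ikzf2, which encodes Helios, was higher in ILC2 (0.76 ± 0.19, adjusted p = 0.0253), a call lost in 6 of 11 fits with a library left out (up to 0.0807). In the list of trafficking genes 5 of 22 were higher in Th2 and 1 in ILC2 (3 higher in ILC2 and 6 in Th2 adjusted over the list alone; camera adjusted p = 0.0649, adjusted p = 0.434 with an estimated correlation). Those higher in Th2 include the lymph node homing receptor Ccr7 (-2.01 ± 0.31, adjusted p = 0.000958) and the trafficking receptor S1pr1 (-2.18 ± 0.44). The integrin Itgb1 (-1.77 ± 0.23) and the skin and lung homing receptor Ccr4 (adjusted p = 0.00727) were higher in Th2 as well. The epithelial retention integrin Itgae was higher in ILC2 (1.59 ± 0.39, adjusted p = 0.0255), and lost the call without ILC2 replicate 1 or 5 or Th2 replicate 5 or 6 (up to 0.0675). Ccr8 gave 1.13 ± 0.32, adjusted p = 0.0540 (0.0148 without ILC2 replicate 1).

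Several chemokine genes and genes for lipid mediators and neuropeptides were higher in ILC2. Of 14 chemokines 4 were higher in ILC2 and 0 in Th2 (5 higher in ILC2 and 0 in Th2 adjusted over the list alone; camera adjusted p = 0.0268, adjusted p = 0.476 with an estimated correlation). The neutrophil attractants Cxcl2 (2.99 ± 0.62, adjusted p = 0.00821) and Cxcl1 (3.41 ± 0.79, adjusted p = 0.0176) were joined by Ccl5 (2.01 ± 0.47) and Cxcl10 (1.44 ± 0.29). ILC2 replicate 2 held 1384 CPM of Cxcl2 against 165 to 252 in the other ILC2 libraries, and without it the value was 2.19. The same 4 were called in June and 0 in August. Cxcl1 lost the call without ILC2 replicate 5 or Th2 replicate 2 (adjusted p up to 0.0622; 4.02 without Th2 replicate 6), and Ccl5 without Th2 replicate 1, 2 or 4 (up to 0.0641). In the lipid mediator and neuropeptide list 8 of 25 members were higher in ILC2 and 2 in Th2 (8 higher in ILC2 and 2 in Th2 adjusted over the list alone; camera adjusted p = 6.49e-05, adjusted p = 0.0114 with an estimated correlation). Besides Alox5, the prostaglandin synthase Ptgs2 was higher by 3.15 ± 0.71 (4.01 and 3.82 without Th2 replicates 1 and 6), the serotonin synthesis enzyme Tph1 by 3.06 ± 0.54, the receptor for vasoactive intestinal peptide Vipr2 by 2.80 ± 0.33 (161 ± 27.6 against 23.4 ± 15.2 CPM) and the leukotriene receptor Cysltr2 by 2.71 ± 0.46. Ramp1, a subunit of the CGRP receptor, differed by 1.99 ± 0.20 and the prostacyclin receptor Ptgir by 1.09 ± 0.22. Vipr1 (-3.19 ± 0.47) and Alox5ap, which presents arachidonate to 5-lipoxygenase (-1.92 ± 0.41), were higher in Th2. The neuromedin U receptor Nmur1 gave 0.84 ± 0.48, adjusted p = 0.391; ILC2 replicate 2 held 2.45 CPM against 20.5 to 39.97 in the other ILC2 libraries, and without it adjusted p was 0.00995.

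Genes of antigen presentation on MHC class II were higher in ILC2 for 5 of 12 members and in Th2 for 0 (8 higher in ILC2 and 0 in Th2 adjusted over the list alone; camera adjusted p = 3.25e-05, adjusted p = 0.168 with an estimated correlation). The invariant chain Cd74 stood at 331 ± 151 CPM in ILC2 and 76.9 ± 52.2 in Th2 (2.01 ± 0.43, adjusted p = 0.0106), H2-Eb1 at 48.3 ± 18.1 against 6.89 ± 6.71 CPM (2.73 ± 0.63; 3.32 and 3.53 without Th2 replicates 1 and 6) and H2-Oa at 16.8 ± 8.29 against 4.17 ± 1.45 CPM (2.00 ± 0.36). Ciita, the class II transactivator (1.70 ± 0.41, adjusted p = 0.0220), and H2-DMb2 (1.49 ± 0.33) were the other 2. H2-Aa (2.00 ± 0.65, adjusted p = 0.0936, and 0.0178 without Th2 replicate 6) and H2-Ab1 (1.72 ± 0.59, adjusted p = 0.118, and 0.0198 without Th2 replicate 6) did not pass the test. Cd74, H2-Eb1, Ciita and H2-DMb2 were called within June and H2-Oa within August, and the call of Ciita was lost in 4 of 11 fits with a library left out (adjusted p up to 0.0773). Without ILC2 replicates 2 and 7 and Th2 replicate 1, 3 members were called. Of markers of antigen-presenting cells, Lyz2 and Cd79b did not pass the test: the macrophage lysozyme Lyz2 stood at 79.1 ± 38.0 CPM in ILC2 and 129 ± 134 in Th2, with 267 and 282 in Th2 replicates 1 and 6, and the B cell receptor subunit Cd79b at 3.71 ± 2.14 against 0.612 ± 0.386 CPM (2.56 ± 0.80, adjusted p = 0.0802, and 0.0139 without ILC2 replicate 2).

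Receptors of natural killer cells and granule genes differed member by member, with 3 of 12 higher in ILC2 and 2 in Th2 (4 higher in ILC2 and 2 in Th2 adjusted over the list alone; camera adjusted p = 0.446, adjusted p = 0.658 with an estimated correlation). The ILC2 marker Klrg1 stood at 342 ± 72.7 against 57.2 ± 20.2 CPM (2.57 ± 0.26, adjusted p = 4.14e-05), Klrb1b differed by 4.68 ± 0.69 and the cathepsin Ctsw by 1.70 ± 0.21. The death ligand Fasl (-4.20 ± 0.33, adjusted p = 6.10e-06) and Nkg7 (-1.79 ± 0.38, adjusted p = 0.0106, and 0.0564 without Th2 replicate 1) were higher in Th2. Arg1, the arginase of ILC2 metabolism, was 12.8-fold higher in ILC2 (856 ± 206 against 72.6 ± 56.7 CPM, adjusted p = 8.76e-05), with 4.17 in June and 2.85 in August (August adjusted p = 0.132). Dgat2, an enzyme of triglyceride synthesis, was higher by 2.73 ± 0.59. In the same list of 26 metabolic genes 3 were higher in Th2, among them the desaturase Scd2 (-0.94 ± 0.25) and the sterol regulator Srebf2 (-0.65 ± 0.17) (2 higher in ILC2 and 4 in Th2 adjusted over the list alone; camera adjusted p = 0.450, adjusted p = 0.658 with an estimated correlation). The calls of Scd2 and Srebf2 were each lost in 7 of 11 fits with a library left out (adjusted p up to 0.0995 and 0.0978).

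Immediate early genes, which respond to activation and also to handling of cells, were higher in ILC2 for 8 of 28 members and in Th2 for 0 (11 higher in ILC2 and 1 in Th2 adjusted over the list alone; camera adjusted p = 0.00139, adjusted p = 0.173 with an estimated correlation). The nuclear receptors Nr4a2 (2.29 ± 0.42, adjusted p = 0.00340) and Nr4a3 (1.65 ± 0.34) led, followed by Fosb (1.57 ± 0.27) and the stress factor Atf3 (2.83-fold, adjusted p = 0.00215). Nr4a1 (1.32 ± 0.34), the signalling regulator Rgs2 (1.19 ± 0.29), Fos (0.82 ± 0.22) and Ier2 (0.79 ± 0.21) lost the call in 6, 3, 7 and 7 of 11 fits with a library left out (adjusted p up to 0.103, 0.0808, 0.109 and 0.109). Without ILC2 replicates 2 and 7 and Th2 replicate 1, 5 members were called, and 3 were called in June alone and 2 in August alone. Interferon-stimulated genes were higher in Th2 for 3 of 18 members and in ILC2 for 0 (0 higher in ILC2 and 4 in Th2 adjusted over the list alone; camera adjusted p = 0.00248, adjusted p = 0.365 with an estimated correlation). The 3 were Oas2 (-3.08 ± 0.70), Ifit2 (-2.54 ± 0.64) and the RNA sensor Ifih1 (-1.22 ± 0.22, adjusted p = 0.00283). Where tested within a single date these 3 did not pass (Ifit2 -2.03 in June and -3.40 in August), while 0 members were called in June and 3 others in August. Oas2 lost the call without ILC2 replicate 5 (0.0512) and Ifit2 in 6 of 11 such fits (up to 0.0814).

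Of 30 cell cycle genes edgeR called 0 in either direction, and 0 adjusted over the list alone. Of these members 1 higher in ILC2 and 10 higher in Th2 had an unadjusted p under 0.05, limma voom called 0 and DESeq2 called 1 in each direction. In August alone edgeR called 3 higher in Th2, with a term for sex 2, and with a library left out at most 1 in each direction; without ILC2 replicates 2 and 7 and Th2 replicate 1 it called 1 higher in ILC2. Camera placed the list lower in ILC2 (adjusted p = 0.00102, adjusted p = 0.488 with an estimated correlation, median -0.68). The proliferation marker Mki67 stood at 223 ± 105 CPM in ILC2 and 324 ± 78.7 in Th2 (-0.77 ± 0.23, adjusted p = 0.0622, with 0.0306 without ILC2 replicate 2 and 0.0385 without Th2 replicate 2). Within August Mki67 was higher in Th2 (-1.49, adjusted p = 0.0406), and within June it did not pass (-0.34, adjusted p = 0.556). Of 18 glycolysis genes only the hexokinase Hk2 was called, higher in Th2 (-0.96 ± 0.26, adjusted p = 0.0415; 0 higher in ILC2 and 2 in Th2 adjusted over the list alone; camera adjusted p = 0.00971, adjusted p = 0.434 with an estimated correlation). It lost the call in 8 of 11 fits with a library left out (up to 0.104).

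**Figure D4:**
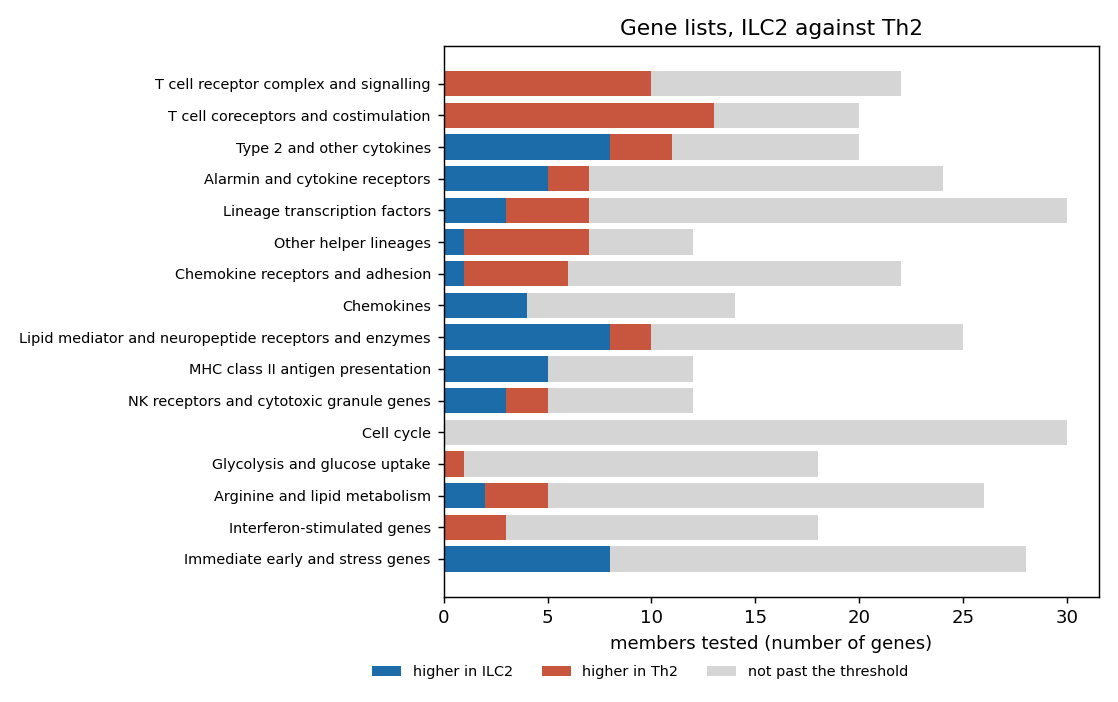
Number of tested members of each of the 16 lists of gene functions that were higher in ILC2, higher in Th2 or not past the adjusted threshold. T cell receptor and costimulation genes were called toward Th2 alone, MHC class II, chemokine and immediate early genes toward ILC2 alone.

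Markers of cells that the sort was meant to exclude were mostly low or variable, and some libraries held far more of them than others. Epithelial markers had medians of 4.41 in Th2 replicate 1, 2.55 in Th2 replicate 6 and 2.85 in ILC2 replicate 4. In every other library the median was at most 0.28 (log2, against the median of the other libraries of the cell type). Among 14 macrophage and dendritic cell genes only Siglecf was called, at 0.175 ± 0.192 against 2.14 ± 1.29 CPM (-3.65 ± 0.84, adjusted p = 0.0151; 0 higher in ILC2 and 1 in Th2 adjusted over the list alone; camera adjusted p = 0.0997, adjusted p = 0.617 with an estimated correlation; median -1.42). Its value was -4.30 and -4.28 without ILC2 replicates 1 and 5. The chitinase-like protein Chil3 stood at 161 ± 100 CPM in ILC2 and 519 ± 665 in Th2 (-1.77 ± 1.15, adjusted p = 0.465). Its value ran from -2.46 without Th2 replicate 4 to -0.71 without Th2 replicate 6, and was 0.48 without ILC2 replicates 2 and 7 and Th2 replicate 1 and 0.61 with the replicate block. Of 5 granulocyte and mast cell genes the mast cell protease Cpa3 was higher in ILC2 (3.49 ± 0.63, 5.52 ± 4.06 against 0.493 ± 0.154 CPM; 1 higher in ILC2 and 0 in Th2 adjusted over the list alone; camera adjusted p = 0.238, adjusted p = 0.434 with an estimated correlation). Of 8 epithelial genes the adhesion protein Cdh1 was higher in Th2 (-1.51 ± 0.40, adjusted p = 0.0373; 0 higher in ILC2 and 1 in Th2 adjusted over the list alone; camera adjusted p = 0.342, adjusted p = 0.658 with an estimated correlation), lost in 7 of 11 fits with a library left out (up to 0.0938). Of 3 B cell genes, 11 stromal and endothelial genes and 2 erythroid genes edgeR called 0; at an unadjusted p under 0.05 stood 1, 0 and 0 of them. In the list for gamma delta, natural killer and CD8 T cells, the receptor constant genes Tcrg-C4 (5.70 ± 0.34, 148 ± 28.3 against 2.88 ± 1.56 CPM) and Tcrg-C1 (2.13 ± 0.58, lost in 8 of 11 fits, up to 0.114) were higher in ILC2. Tcrg-C2 (-3.52 ± 0.44) and the CD8 chain Cd8b1 (-5.42 ± 0.58, and -6.15 without ILC2 replicate 2) were higher in Th2 (2 higher in ILC2 and 2 in Th2 adjusted over the list alone; camera adjusted p = 0.318, adjusted p = 0.446 with an estimated correlation). Tcrg-C1 and Tcrg-C2 are close copies, so the division of reads between them is uncertain.

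The 2 sort dates, which stand for independent infections, were compared with cell type in the model, and the Helios gene Ikzf2 came nearest to a difference. No gene passed the adjusted threshold in edgeR for August against June, where 312 of 13560 genes had an unadjusted p under 0.05. Limma voom called 0 and DESeq2 called 2, Ikzf2 and the natural killer receptor Klrc2. Ikzf2 was 1.19 ± 0.19 higher in August (edgeR adjusted p = 0.349), with 57.6 ± 9.30 CPM (n = 4) and 109 ± 22.4 (n = 2) in ILC2 and 29.6 ± 5.11 (n = 3) and 82.1 ± 22.0 (n = 2) in Th2. Impg2 (2.19 ± 0.52) and Mki67 (-1.04 ± 0.24) were among the next by p and did not pass the test. Of simulated 2-fold and 4-fold date differences 16.5% and 77.1% were recovered, so smaller differences than these are seldom detectable here.

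Whether the difference between ILC2 and Th2 changed from June to August was tested with an interaction term, positive where the ILC2 excess was larger in August. Treml2, a receptor of the TREM family, went from 12.1 ± 1.85 CPM in June ILC2 to 2.94 ± 1.02 in August ILC2, and from 3.19 ± 0.49 to 14.4 ± 2.20 in Th2 (-4.20 ± 0.47, adjusted p = 0.0176). The gene Rnd3 had the opposite course, 4.57 ± 0.90 and 13.5 ± 4.52 CPM in ILC2 and 28.0 ± 6.97 and 7.59 ± 1.32 in Th2 (3.45 ± 0.46, adjusted p = 0.0475). These 2 genes were the only ones called by edgeR, with 1033 at an unadjusted p under 0.05; limma voom called the same 2 and DESeq2 called 68. Next by p were the interferon-induced Ifit1 (-4.13 ± 0.64, adjusted p = 0.108) and the pseudogene Gm12250 (-4.12 ± 0.65). Leaving out single June libraries gave Treml2 alone without ILC2 replicate 2 or 4, and 0 genes without any of the others. Without an August library its cell type kept a single library of that date, so the counts of those fits are not weighed here. Of simulated 4-fold interactions 3.1% were recovered and of 2-fold ones 0%, so the count says little about smaller differences.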

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

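The tests of explanations in this part, and the tests of gene lists by sort date, were chosen after the results were seen. The 148 genes named in the text and measures of the libraries were checked in each cell type. Among these 304 sets of values, 28 held 1 library far from the others by Dixon's criterion. Of the 28, 16 lay in ILC2 replicate 2, 4 in Th2 replicate 1 and 3 in ILC2 replicate 7. The criterion flags about 1 in 20 by chance, but some genes were named after their values were seen. The 28 can therefore not be set against that rate.

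In ILC2 replicate 2 the secreted factors Il13 (3243 CPM), Il5 (446 CPM), Csf2 (233 CPM), Cxcl2 (1384 CPM) and the neuropeptide gene Calca (222 CPM) were far above the other ILC2 libraries. Lat (99.6), Pdcd1 (275), Ccdc184 (84.8), Zbp1 (50.1) and Trbc1 (147 CPM) were also high. Tnf (7.57), Nmur1 (2.45), Alox5ap (0.765) and Cntn1 (90.2 CPM) were far below, as were its mitochondrial share (28.4%) and mitochondrial rRNA share (25.9%). Il13, Il5, Csf2 and Cxcl2 were high together while Tnf stood at 7.57 against 31.3 to 61.7 CPM, so the library was not raised in every cytokine.

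Of 34 tested cytokines and chemokines, 4 met the criterion as high in that library, Il13, Il5, Csf2 and Cxcl2, with a median excess of 2.56 and a range of 1.60 to 2.87 on the log2 scale; Cxcl3 (826 CPM against 32.7 to 248) and Il6 (187 against 30.8 to 75.8) were highest there too without meeting it, and the tests cover the 4. A lower mitochondrial share would raise all other genes alike, and TMM scaling already takes up such a shift (factor 1.33 in that library). Over non-mitochondrial counts the median excess was 2.61 (lower quartile 2.35). A bias by gene length would follow the trend on exonic length. That trend ran from 0.29 for the shortest genes to -0.14 for the longest. After its removal the residual was 2.35 (lower quartile 2.03). The 4 were picked for their large excess, which neither adjustment could have removed. The 2 results are therefore no test of these causes, and show only that both adjustments are small beside the excess of the 4. The labels give no group that sets this library apart, so no biological explanation was tested.

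ILC2 libraries carried T cell receptor constant transcripts without the alpha chain: Trac stood at 2.58 ± 1.34 CPM in ILC2 and 345 ± 58.0 in Th2, Trbc2 at 119.7 ± 29.8 and 287 ± 43.2, and Tcrg-C4 at 148 ± 28.3 and 2.88 ± 1.56. Carry-over of alpha beta T cells would bring Trac in proportion, but the lowest ratio of Trbc1 or Trbc2 to Trac in an ILC2 library was 18.2 times the Th2 median. Carry-over of gamma delta T cells would tie Cd3e to Tcrg-C4, yet their ratio varied 15.5-fold among ILC2 libraries while Tcrg-C4 itself varied 1.76-fold. Cd3e was low there, from 3.15 to 35.7 CPM. This argues only against such cells as the source of all of both transcripts, and a part from them stays open. The delta chain gene Trdc did not match a gene name and could not be looked at. Reads moved between copies would leave the sum of the 4 Tcrg constant genes equal, but the lowest ILC2 sum was 2.76 times the highest Th2 sum. Transcription of these loci in ILC2 may be the source, a hypothesis found and tested on the same data.

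The MHC class II genes Cd74, H2-Eb1, H2-Oa, Ciita and H2-DMb2 were higher in ILC2 with a median of 2.00. Macrophages would bring their own genes with them. Of 10 macrophage genes, 9 in Th2 replicate 1 and 10 in Th2 replicate 6 lay above every ILC2 library, and the second highest Th2 level was a median of 3.03 times the highest ILC2 level. Yet Cd74 stood at 152 and 111 CPM in those Th2 libraries against 205 to 547 in ILC2. Of the 5 class II genes 4 were lower there than in every ILC2 library; Ciita was 1.11 CPM in ILC2 replicate 7 against 1.23 and 1.29. The 5 were picked as called higher in ILC2, which partly fixes that order. H2-Aa and H2-Ab1 were not among them, and passed in edgeR without Th2 replicate 6 (adjusted p = 0.0178 and 0.0198). The order of the 5 is therefore no independent test. The macrophage genes argue only against macrophages as the whole source of the excess over Th2 replicates 1 and 6, and a part from them stays open. B cells would bring their own abundant transcripts, which reached at most 2.39% of the Cd74 level in an ILC2 library. Dendritic cells cannot be told apart from expression by ILC2: the median of Flt3, Zbtb46, Xcr1 and Itgax was -0.31, but baselines over 1 CPM could hide a small share. A difference of cell type stays open beside them, and the sort excluded lineage-positive cells.

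Other libraries stood apart in single genes. ILC2 replicate 7 was high in Adam12 (111 CPM against 68.6 to 74.7), Impg2 (4.25) and Cxcr5 (1.81 CPM). Th2 replicate 1 was high in Angptl2 (92.7 CPM against 22.3 to 24.3) and Cd8b1 (9.16) and low in Tcf7 (54.0 against 196 to 272) and Pde7b (0.273 CPM). ILC2 replicate 5 was low in Alox5 (57.3) and high in St8sia1 (5.02 CPM), ILC2 replicate 4 low in Ifng (0.138), ILC2 replicate 1 high in Ifih1 (13.7) and Th2 replicate 5 low in Ccr8 (95.1 CPM). Tcf7 without Th2 replicate 1 was higher in Th2 with adjusted p = 0.00187 (0.207 at most over all libraries left out).

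The difference between ILC2 and Th2 itself differed between June and August for Treml2 (-4.20) and Rnd3 (3.45) by the interaction test. With single June libraries left out, only Treml2 was called, and only without ILC2 replicate 2 or 4. Among lists it differed for interferon-stimulated genes (median -1.11, fry adjusted p = 0.000287) and for natural killer receptors and granule genes (median -2.14, adjusted p = 0.0307). The difference for the natural killer list was kept in only 4 of 11 fits with a library left out (up to 0.159).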

How the results depend on the processing

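The omission of mitochondrial genes, the sex term and the omission of 3 libraries were chosen after seeing the data; the other alternatives were set before. All genes called between ILC2 and Th2 kept their direction under every alternative in which they were tested. The 983 calls became 987 with RLE scaling (971 shared), 977 with upper quartile (959), 1090 without a filter (879), 953 with limma voom (877), 869 with thinned counts (815), 1066 without a date term (955), 1003 without mitochondrial genes (980), 1115 with a sex term (967) and 1067 without the 3 libraries (799). With each library left out they ran from 731 (without Th2 replicate 5) to 1102 (without ILC2 replicate 2).

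Counts of genes higher in ILC2 and in Th2, 530 and 453, moved by more than 1.5 times to 825 and 803 with DESeq2, 296 and 272 when tested against a fold of 1.5, 310 and 272 in June alone and 126 and 113 in August alone, where fewer libraries were tested. Members of the 16 function lists fell from 48 higher in ILC2 to 31 against a fold of 1.5 and 16 in August alone, and from 54 higher in Th2 to 32 in August alone. The causes were not tested where no construction shows them.

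For the sort date DESeq2 called 2 genes higher, Ikzf2 (adjusted p = 0.000488) and Klrc2 (0.0313), against 0 with edgeR; every other alternative called 0. For the interaction, 1 gene higher and 1 lower became 4 lower without a filter, 19 and 49 with DESeq2, 0 higher against a fold of 1.5, and 0 and 0 with thinned counts. Leaving out each library gave 0 to 3 higher and 0 to 74 lower, with 3 and 74 without ILC2 replicate 5. That fit kept 1 August library of ILC2, so its counts cannot show how many genes differ. With single June libraries left out, 0 genes were higher and at most 1 was lower. The cause of the larger counts was not tested.

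Numbers are shared by 4 replicates of both cell types but do not pair them: correlations of the deviations from the cell type mean, across genes, were -0.02, -0.17, -0.30 and 0.12 for numbers 1, 2, 4 and 5, and libraries of 3 of the 4 numbers differ in Xist and Y-linked genes. With the replicate block as a factor 288 and 253 genes were called (521 shared), 0 and 0 for the interaction, and 35 list members higher in Th2; with duplicateCorrelation 909 genes were called (consensus -0.04).

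Of 148 named genes 114 were called. Of the 3837 values of named genes under 26 alternatives, 3430 kept their side of the threshold, 353 lost the call, 54 gained it and 0 reversed. A reversal was counted only where the main fit or the alternative called the gene. Among values called in neither fit, 41 changed sign. Of the called genes, 41 were kept under every alternative. Of the 114, 87 were called without any 1 library, and 27 were lost without at least 1. In June 79 of 113 and in August 51 of 114 passed the threshold, with the direction of all kept.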

Other observations

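All tests in this part were set out after the results were seen. Interferon-stimulated genes moved in opposite directions in ILC2 and Th2 between the sort dates. In ILC2 15 of 18 members were lower in August (median -0.44, fry adjusted p = 0.0122), and in Th2 1 of 18 was lower (median 0.72, adjusted p = 0.000531). Ifit1 went from 4.37 ± 1.41 to 1.04 ± 0.41 CPM in ILC2 and from 3.05 ± 1.04 to 13.1 ± 2.42 in Th2. A difference between the cell types in this response, the hypothesis tested, gave fry adjusted p = 0.000287, and at most 0.00196 with each June library left out. Without an August library its cell type kept a single library of that date, so those p-values are not given. The change within ILC2 was lost without ILC2 replicate 5, where 1 August ILC2 library was left. The same limit holds for fits without an August library in the lists below. Each cell type had 2 August libraries. Those of ILC2 also differed from June in sex-linked genes and in markers of other cell types, and those of Th2 were lowest in erythroid genes, as given below. The date cannot be told apart from these.

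Natural killer receptors and granule genes rose from June to August in Th2 (1 of 12 members lower, median 1.29, adjusted p = 0.0252), as did genes of other helper lineages (1 of 12 lower, median 1.48, adjusted p = 0.0252). Foxp3 went from 7.13 ± 4.505 to 40.0 ± 16.5 CPM and Cxcr3 from 5.31 ± 1.49 to 23.99 ± 1.91 in Th2, and Gzmb from 24.1 ± 34.2 to 65.7 ± 38.7. For the first list the hypothesis of a difference between the cell types gave adjusted p = 0.0307, kept in 4 of 11 fits with a library left out (up to 0.159), so it cannot be told apart from the spread between libraries. For the other helper lineages the difference gave 0.297. The 2 changes within Th2 were kept in 7 and 8 of 11 such fits, up to 0.176 and 0.128. In the same Th2 libraries the 2 tested erythroid genes had medians of -0.55, 2.85 and 2.21 in June and -1.85 and -1.63 in August. These are log2 values against the median of the other libraries of the cell type, and the date was not tested for them. Both August libraries were lowest, so the dates may differ in more than these lists.

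Cell cycle genes were lower in August in ILC2 for 29 of 30 members (median -1.57, adjusted p = 0.0289, kept in 4 of 11 fits with a library left out, up to 0.246). Single members did not pass the date test in edgeR; Mki67 stood at 288 ± 41.4 CPM in June and 93.8 ± 8.98 in August and Top2a at 196 ± 68.4 and 89.2 ± 0.34. In Th2 the list gave adjusted p = 0.947, and the hypothesis that the cell types differ gave 0.0758, which did not pass the threshold (0.00607 without Th2 replicate 1). The August ILC2 libraries differed from those of June in more than the date. Both were Xist-high while 3 of the 4 June libraries were Y-high. Macrophage and dendritic cell markers had medians of -0.84 and -0.78 in the August libraries and -0.09 to 0.74 in June. Epithelial markers had -2.04 and -3.86 and -0.24 to 2.85 (log2, against the median of the other libraries of the cell type). The date cannot be told apart from these in ILC2.

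Of the T cell receptor segment families with at least 8 tested genes, 3 were higher in Th2 in every tested member. They were 13 of 13 Trbv, 19 of 19 Traj and 12 of 12 Trav segments, with medians of -7.00, -6.83 and -7.50. The low count filter keeps a gene with enough counts in 1 cell type alone. Segments this low in ILC2 were thus tested because of their Th2 level. Neither these counts nor the camera values of the 3 families are independent support for a difference. The 13 tested Trbj segments had a median of 0.75, and no test compared the families with each other. Camera with an estimated correlation gave adjusted p of 0.0104, 0.0276, 0.0144 and 0.994 in that order over 211 families of genes named alike; the 4 were chosen after their values were seen.

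For ILC2 against Th2, only the real split of the 11 libraries, 1 of 100, gave 983 genes, and the highest other gave 1. Every other split mixed the cell types, so the difference between them widened the spread within its groups and lowered its count. These splits therefore do not show how many genes chance would give. For the sort dates the real count is 0, which all 100 of 100 splits reach by construction, so the splits say nothing about the date. The highest other gave 71 genes with ILC2 replicates 3 and 4 and Th2 replicates 1 and 6 against the rest, which points to a structure of the samples other than the date. These 4 libraries are among the 5 with high Y-linked genes, ILC2 replicate 2 being the fifth. In stromal and endothelial markers every library outside these 4 had at most 0.33 (log2, against the median of the other libraries of its cell type). These 4 were the highest there, with medians of 1.06, 1.90, 1.83 and 2.32. Macrophage and dendritic cell markers had 0.31, 0.74, 2.19 and 2.61 in them, the 2 highest of each cell type. What sets these libraries apart was not tested.

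Xist was high in ILC2 replicates 1, 5 and 7 and Th2 replicates 2, 4 and 5, and Y-linked genes in the others. In June 1 ILC2 library and 2 Th2 libraries were Xist-high, and 3 ILC2 and 1 Th2 were Y-high, so no reassignment of numbers within June pairs every Th2 library with an ILC2 library of the same sex.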
